A study of Mus musculus with 2 samples.

How the data were processed

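Total RNA of the cytosolic fraction of mouse macrophages was measured in 2 libraries of 1 group, each from 1 µg of RNA with a size range of 250 to 400, per the labels. For each library 3 tables were used: a gene table and a transcript table made from an alignment to the transcriptome, and a transcript table made from the reads. The text deposited beside the tables names the mm10 assembly and the GENCODE M21 annotation. The aligner and the quantifiers are not given in the sources used here, nor is strandedness.

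The authors deposited expected counts, estimated per gene or transcript and not scaled by depth, per the file headers. The deposited TPM values are scaled to a fixed total over all features of a table, spike-ins and structured RNAs included, and corrected for effective length. The deposited FPKM values are scaled by effective length and by the number of mapped fragments, per the file headers. The deposited percent values give each transcript's part of its gene's TPM, per the file headers. Short RNAs have short effective lengths, which raises their TPM, so that 7SL RNA lowers the TPM of every other gene without changing ratios within a library. The gene table has 81881 features, of which 55536 are annotated genes that all matched the annotation, 26248 are transfer RNAs and 97 are spike-ins. Transfer RNAs and spike-ins were left out of tests and of the library sizes used in them. Shares of a library's TPM or expected counts are of all features, these included. Spike-ins held 0.110% and 0.112% of expected counts in replicates 1 and 2.

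Levels were taken from deposited gene TPM. A gene was called detected at a TPM of at least 1 in both replicates. Levels were banded as high (at least 100), moderate (10 to under 100), low (1 to under 10) and not detected, each in both replicates, and a gene whose replicates fell in different bands was put in the lower one. Not detected is thus a band of TPM and does not mean that a gene had no counts. Gene lists, bands, the main tests and the rule for named genes were fixed before the data were examined, and tests, symbols and examples chosen later are named as such where they appear. The rule took the 20 genes with the highest mean TPM, up to 6 of the highest and 3 of the lowest members of each list, 16 preset genes (Tnf, Il1b, Il6, Il12b, Il10, Ifnb1, Cxcl10, Nfkbia, Tnfaip3, Irak3, Nos2, Acod1, Ptgs2, Tlr4, Malat1 and Neat1), the 10 largest folds in each direction between replicates, and up to 6 genes on each side of the transcript comparison. Part of the genes the rule allows are printed, and some are not reported here. The 29 lists covered macrophage identity, 7 classes of lipid A response gene, the TLR4 pathway, alternative activation, antigen presentation, lysosomes, glycolysis, cholesterol and lipid, proliferation, 3 classes of long noncoding RNA, structured RNAs, histones, mitochondrial messages, ribosomal proteins and 7 other lineages. Of all list symbols 2, Rn45s and Ahsp, had no match in the annotation.

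List contrasts are differences of medians of log2(TPM + 0.1) within a library, given as mean and SD over the replicates. With 1 group there is no test between groups, and genes were not used as replicates. Replicate spread is the SD over detected genes of the log2 ratio of TPM + 1, divided by the square root of the number of libraries. For the test between replicates, expected counts were rounded to whole numbers first and library sizes were scaled by TMM in edgeR. A two-sided exact binomial test was run per gene with a mean count of at least 10, with Benjamini-Hochberg adjustment, a threshold of 0.05 and a fold of at least 2. It holds counting error only, so edgeR's exact test was also run with an assumed biological coefficient of variation of 0.1 and, chosen after seeing the data, 0.2. List shifts are medians of log2 ratios over detected members, placed among 10000 random lists matched on mean expression in 20 bins. A gene with no count in a library was set to a floor of 3 counts, which is 0.0467 and 0.0607 CPM in replicates 1 and 2 by unscaled library totals. Fold bounds against that floor use library sizes scaled by TMM. Floors and intervals cover counting error only.

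The rounded expected counts summed to 64187219 and 49429864, which gives replicate 1 the smaller counting error. The tests were tried on simulated counts with the means and library sizes of these libraries and 200 changed genes. For the comparison of replicate 2 with replicate 1, over 13304 genes with no variation beyond counting, the exact binomial test found 97% of genes changed 4-fold and 87% of those changed 3-fold, and called 1 unchanged gene. With a coefficient of variation of 0.2 over 13283 genes it called 361 unchanged genes, and edgeR's exact test at 0.2 called 6 while finding 77% at 4-fold and 41% at 3-fold. For list shifts over 9302 genes, 5% of 200 unshifted simulated lists and 99% of lists shifted by 0.5 fell outside the central 95%. Members of these simulated lists varied independently, so the 5% follows from how they were drawn and does not cover genes that move together. The correction for length, GC content and expression first took out part of a simulated shift, so it was changed to leave list members out of the trend before it was run on these libraries, after which it returned -1.03 for a shift of -1 over 9302 genes. The simulated trend used random values in place of length and GC content and had a form that the correction fits. It therefore does not show how well the correction takes out a real trend.

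Alternatives covered pseudocounts, filters, units, scaling, the read-based table and leaving out each replicate. Copies were compared by the sequences of the annotated transcripts. Coordinates are on mm10, counted from 1. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 (size factors as an alternative scaling), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.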

Results

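The data describe macrophages grown from mouse bone marrow (strain C57BL/6J, primary cells) that met lipid A, the part of bacterial lipopolysaccharide that the receptor TLR4 binds, at 2 times. The cells received 100 ng/ml lipid A for 12 h, were washed and rested for 12 h, and then received 100 ng/ml lipid A for 75 min. RNA of the cytosolic fraction was depleted of ribosomal RNA and sequenced as total RNA. The series forms 1 group with 2 biological replicates, so every level below is a mean ± SD (n = 2) in TPM, a length-corrected share of all transcripts in a library, unless another unit is named. The libraries held 64187219 and 49429864 expected counts on annotated genes in replicates 1 and 2. No untreated or singly treated library was analysed here, so the levels do not measure induction or tolerance. The labels give the replicates separate biosample records and the same donor code, which may stand for the strain; p-values between them then measure only the spread between these samples, which may be technical.

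Among messenger RNAs, those of ferritin were the most abundant in the cytosol of these cells. Fth1 and Ftl1, the heavy and light chains of ferritin, stood at 19138 ± 4932 and 7545 ± 1789 (n = 2). Ccl5, a chemokine that attracts T cells and monocytes, reached 4643 ± 487, and Saa3, an acute phase apolipoprotein, reached 4170 ± 2253. Tmsb4x, which binds actin monomers, stood at 4622 ± 233 and Actb, cytoplasmic actin, at 3183 ± 450. Psap, the precursor of the saposins, Ctsd and Ctsb, lysosomal proteases, and Lyz2, lysozyme, stood at 3055 ± 176, 2299 ± 143, 1711 ± 205 and 3014 ± 143. B2m, H2-K1 and H2-D1, which form class I antigen-presenting molecules, stood at 3391 ± 465, 2073 ± 341 and 1455 ± 249, and Gpnmb, a glycoprotein of macrophage endosomes, at 1309 ± 158. On the mm10 assembly, Fth1 lies on chromosome 19 from 9980598 to 9985098 and Ccl5 on chromosome 11 from 83525778 to 83530518.

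Structured noncoding RNAs set the scale of the TPM values. Rn7s2 and Rn7s1, 7SL RNA of the signal recognition particle, stood at 308905 ± 9067 and 307243 ± 9626, and since their annotated transcripts are identical in sequence the split between them is uncertain. Rn7sk, a regulator of transcription elongation, stood at 46460 ± 28892, and Rpph1, the RNA of ribonuclease P, at 34331 ± 4076. Rmrp, the RNA of ribonuclease MRP, is annotated as 2 overlapping genes, a ribozyme at 8081 ± 5556 and a long noncoding RNA at 2185 ± 2073. Together 7SL held 62.9% and 60.3% of TPM in replicates 1 and 2 and 9.92% and 9.43% of expected counts. Protein-coding genes held 29.9% and 26.2% of TPM and 87.9% and 87.1% of expected counts. The TPM of a gene therefore depends on the scale and the table: Tnf stood at 1032 here, at 3645 with TPM rescaled to protein-coding genes and at 520 in the read-based table.

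In all, 9302 of 55536 annotated genes reached a TPM of 1 in both replicates. Of these, 8812 were protein-coding, 189 were long noncoding, 236 were pseudogenes and 65 were of other classes. A further 546 genes reached that level in a single replicate. A TPM of 10 was reached in both replicates by 3555 genes, and a TPM of 100 by 404, of which 386 were protein-coding. The number of detected genes depended on the rule and the table. It was 5569 at a TPM minimum of 5 and 7965 in the read-based table. With TPM rescaled to protein-coding genes it was 11174, and at an expected count of at least 10 in both replicates 12815.

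Markers of macrophages were abundant and those of other bone marrow lineages were mostly at or near 0. The 24 macrophage identity genes had a median of 157 ± 6.92 (n = 2), with 13 high (at least 100 in both replicates), 10 moderate (10 to under 100) and Cx3cr1, the fractalkine receptor, not detected (under 1) at 0.080 ± 0.042. Lyz2 and Fcer1g, a signalling adaptor of activating receptors, stood at 3014 ± 143 and 1298 ± 56.6. Ctss, a protease of antigen processing, stood at 1114 ± 50.4, Lgals3, a lectin, at 703 ± 329, Mpeg1, a pore-forming protein, at 652 ± 121, and Cd68, a lysosomal glycoprotein, at 612 ± 105. Cebpa, a transcription factor of the myeloid lineage, was the lowest detected member at 12.2 ± 0.042. Among 91 markers of other lineages, 82 lay under 1 in both replicates, 23 had no count in either, and 7 reached 1 in both. Csf3r, the receptor for granulocyte colony-stimulating factor, which monocytes also express, was the single such marker at 10 or more, at 29.1 ± 2.43. S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, stood at 5.22 ± 2.95 and 3.28 ± 1.51, Vwf and Kdr, of endothelium, at 2.32 ± 1.15 and 2.23 ± 0.156, Mmp8, a neutrophil collagenase, at 1.73 ± 0.354, and Cd79b, of the B cell receptor, at 1.40 ± 0.467. List medians were 0.0050 ± 0.0071 for T and natural killer cells, 0.0175 ± 0.0247 for B cells, 0.070 ± 0.042 for neutrophils, 0.0075 ± 0.0106 for mast cells and basophils, 0.080 ± 0.042 for dendritic cells and 0.015 ± 0.0071 for stroma and endothelium, and 0 in both replicates for erythroid cells and megakaryocytes. On the log2(TPM + 0.1) scale the macrophage median exceeded that of the other lineages by 10.39 ± 0.02 (n = 2). With one median at the floor that difference follows the pseudocount, and it was 7.25 with a pseudocount of 1 and 6.51 over members at a TPM of 1 or more.

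Cytokine messages ranged from high to not detected, while a group of antimicrobial and effector genes had the higher median. Tnf, tumour necrosis factor, stood at 1032 ± 273 (n = 2), and Il1a and Il1b, the interleukin-1 ligands, at 423 ± 228 and 326 ± 124. Tnfsf9, a ligand that costimulates T cells, stood at 263 and 89.4 in replicates 1 and 2, Ebi3, a subunit of interleukin-27, at 84.1 ± 0.177, and Il15 at 37.9 ± 7.59. Il6 stood at 14.5 ± 11.0, Il12b, the shared subunit of interleukins 12 and 23, at 9.48 ± 5.15, and Ifnb1, interferon beta, at 9.54 ± 5.32. Csf3, Il12a and Lif were not detected, at 0.175 ± 0.050, 0.110 ± 0.071 and 0.090 ± 0.085. Of the 20 cytokine genes 3 were high, 5 moderate, 7 low (1 to under 10) and 5 not detected, with a median of 9.75 ± 4.89. All 20 had a mean expected count of at least 10, so those not detected by TPM still held counts. Of 24 effector genes 7 were high, 9 moderate, 3 low and 5 not detected, with a median of 25.9 ± 0.120. Beside Saa3, the highest effectors were Acod1, which makes itaconate, at 850 ± 180, Sod2, mitochondrial superoxide dismutase, at 248 ± 40.5, Clec4e, a receptor for mycobacterial glycolipid, at 226 ± 24.1, and Cybb and Ncf1, of the phagocyte oxidase, at 207 ± 13.6 and 147 ± 11.2. Ptgs2, inducible cyclooxygenase, stood at 45.2 ± 22.3 and Nos2, inducible nitric oxide synthase, at 2.67 ± 0.615, while Camp, cathelicidin, stood at 0.110 ± 0.014. The effector median exceeded the cytokine median by 1.39 ± 0.89 on the log2(TPM + 0.1) scale (n = 2). That difference was 0.77 in replicate 1 and 2.02 in replicate 2, and no test was run on it.

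Chemokine messages were abundant as a group. Of 18 chemokine genes 8 were high, 4 moderate, 3 low and 3 not detected, with a median of 102 ± 31.3 (n = 2). Below Ccl5 came Ccl3 and Ccl4, the macrophage inflammatory proteins, at 950 ± 466 and 918 ± 371, Cxcl10, an interferon-inducible chemokine, at 682 ± 112, and the monocyte attractants Ccl7 and Ccl2 at 446 ± 141 and 385 ± 163. Cxcl3, Ccl24 and Ccl17 were not detected, at 0.690 ± 0.424, 0.320 ± 0.170 and 0.020 ± 0.028.

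Interferon-stimulated messages stood higher at 75 min after the last lipid A dose than immediate early messages did. All 34 interferon-stimulated genes were detected, 19 of them high, 14 moderate and 1 low, with a median of 117 ± 5.77 (n = 2). Ifit2 and Ifit3, of an interferon-induced family that acts on viral RNA, stood at 719 ± 47.9 and 477 ± 3.15. Rsad2, viperin, stood at 695 ± 47.3, Irf7, a transcription factor of the interferon response, at 610 ± 68.9, Isg15, a ubiquitin-like modifier, at 533 ± 34.6, and Bst2, tetherin, at 478 ± 33.8. The lowest members were Irf9, Mx2 and Oas2 at 24.5 ± 3.59, 19.2 ± 0.304 and 10.8 ± 1.38. Of 19 immediate early genes 3 were high, 11 moderate, 4 low and 1 not detected, with a median of 39.3 ± 8.15. The transcription factor genes Klf6, Junb, Egr1 and Atf3 stood at 264 ± 93.0, 214 ± 40.7, 171 ± 96.9 and 139 ± 67.9, and Dusp1, a phosphatase that acts on MAP kinases, at 109 ± 66.0. Fosb, a partner of Jun proteins, did not reach a TPM of 1 in both replicates, at 1.82 and 0.180 in replicates 1 and 2. The immediate early median lay at -1.59 ± 0.23 relative to the interferon-stimulated median on the log2(TPM + 0.1) scale, with -1.43 and -1.75 in the 2 replicates.

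Most genes of NF-kB subunits and inhibitors and most feedback regulators were moderate or high. Nfkbia and Nfkbiz, inhibitor-family proteins of NF-kB, stood at 450 ± 154 and 215 ± 71.0 (n = 2), and Tnfaip3, the deubiquitinase A20, at 227 ± 73.9. Of the 18 genes of NF-kB subunits and inhibitors 3 were high, 12 moderate and 3 low, with a median of 36.7 ± 7.37. Of 24 anti-inflammatory and feedback genes 3 were high, 13 moderate, 4 low and 4 not detected, with a median of 22.7 ± 1.91. Zfp36, which destabilises cytokine messages, stood at 334 ± 145, Socs3, a suppressor of cytokine signalling, at 190 ± 72.0, and Tgfb1 at 108 ± 7.49. Il10, an anti-inflammatory cytokine, stood at 23.9 ± 23.6 and Irak3, an inhibitory kinase-like protein of TLR signalling, at 14.6 ± 0.297. Of 26 TLR4 pathway genes 1 was high, 14 were moderate, 10 low and 1 not detected, with a median of 12.3 ± 1.77. Cd14, a coreceptor, stood at 224 ± 65.0, Tlr4 at 16.6 ± 1.94, and Lbp, a lipopolysaccharide-binding protein, at 0.745 ± 0.262.

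Lysosomal messages had a high median, and the medians of alternative activation and proliferation genes were among the lowest. The 18 lysosomal genes had a median of 242.5 ± 2.03 (n = 2), the 18 antigen presentation genes one of 46.3 ± 2.04, the 18 glycolysis genes one of 50.8 ± 3.69 and the 20 cholesterol and lipid genes one of 29.6 ± 1.64. Gapdh, a glycolytic enzyme, stood at 323 ± 78.1, Fabp5, a fatty acid-binding protein, at 1146 ± 396, and Apoe, an apolipoprotein, at 1141 ± 282. The 12 alternative activation genes had a median of 0.438 ± 0.230, with 7 not detected. Stab1, a scavenger receptor, was the highest of them at 36.5 ± 14.0, Arg1, arginase, stood at 0.015 ± 0.021, and Retnla, a secreted resistin-like protein, had a TPM of 0 in both replicates. The 20 proliferation genes had a median of 1.70 ± 0.255, led by Pcna, the replication clamp, at 62.9 ± 7.88 and Mki67, a marker of cycling cells, at 14.9 ± 2.88.

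**Figure D1:**
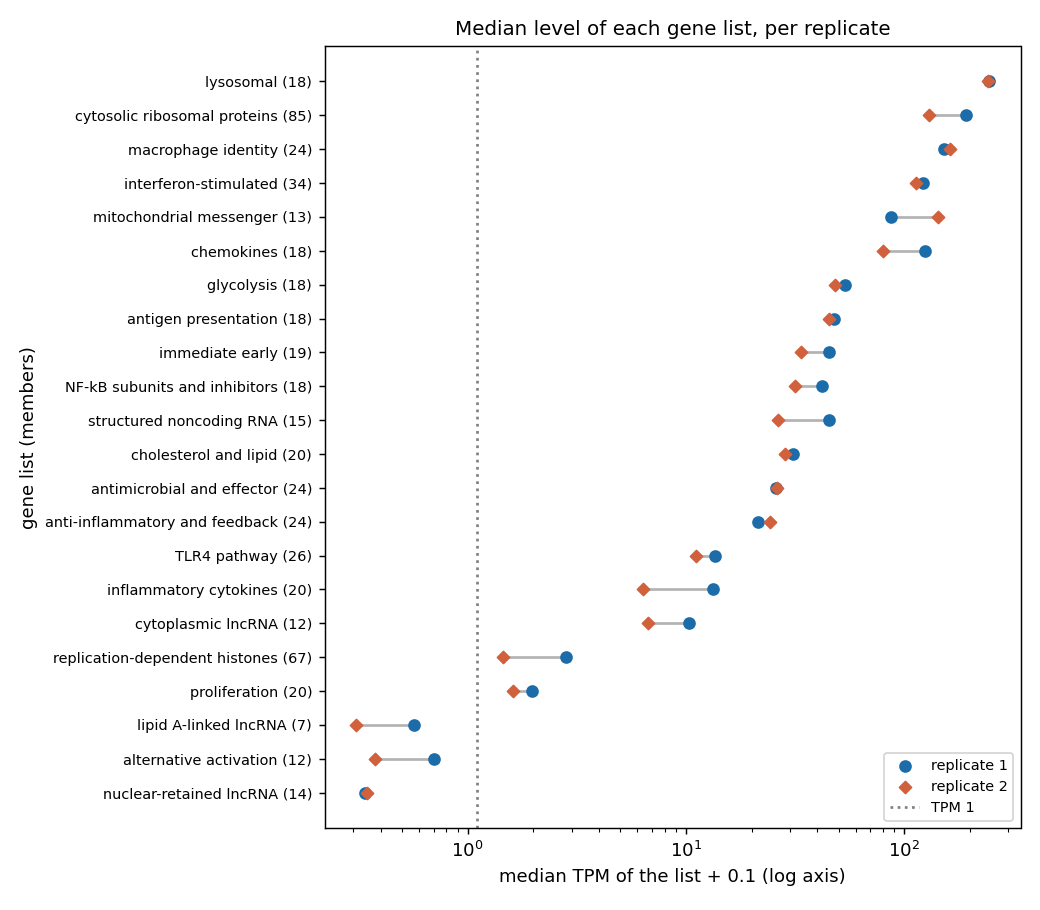
Median TPM of each gene list plus 0.1 on a log axis, with replicate 1 as circles, replicate 2 as diamonds and list sizes in brackets. Lysosomal genes had the highest median, 242.5, and nuclear-retained long noncoding RNAs, at 0.2425, alternative activation genes and lipid A-linked long noncoding RNAs lay under 1.

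**Figure D2:**
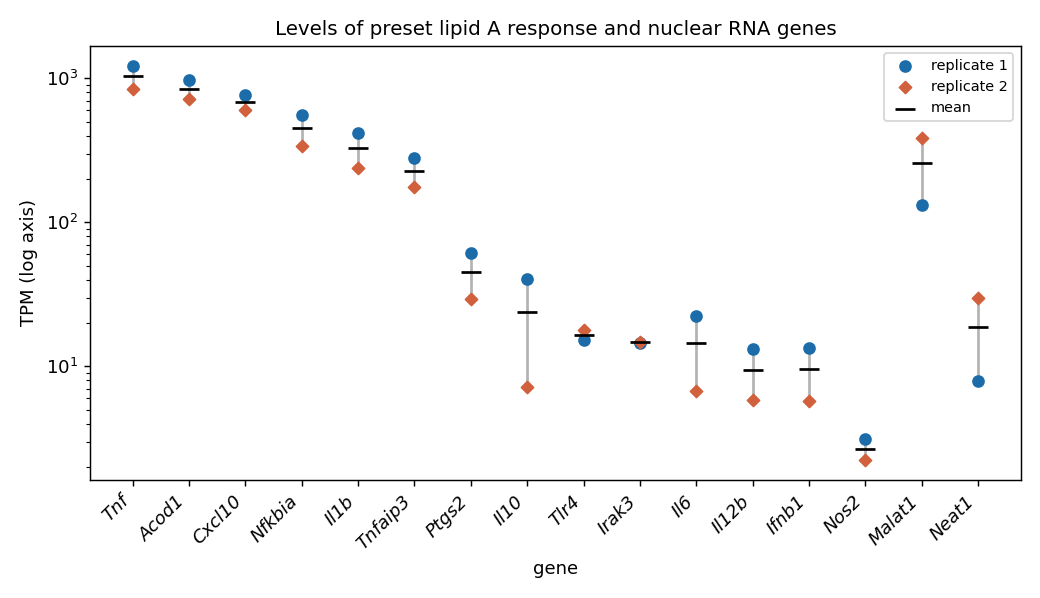
TPM on a log axis of 14 lipid A response and pathway genes and of Malat1 and Neat1, with replicate 1 as circles, replicate 2 as diamonds and the mean as a bar. Tnf had the highest mean, 1032, and Il10 the widest gap among the response genes, from 40.6 to 7.23.

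Cytoplasmic long noncoding RNAs were more abundant than nuclear-retained ones when lists were compared by their medians, but the most abundant nuclear RNA exceeded every cytoplasmic list member. The labels name the fraction as cytosol. No nuclear library was analysed here, so this comparison cannot tell exclusion from the fraction apart from genes these cells do not express. The 12 cytoplasmic RNAs had a median of 8.42 ± 2.56 (n = 2), with 4 moderate, 6 low and 2 not detected. They were led by 2900097C17Rik at 56.2 ± 8.58 and by the small nucleolar RNA hosts Gas5 and Zfas1 at 42.3 ± 15.3 and 33.3 ± 11.3. The 14 nuclear-retained RNAs had a median of 0.2425 ± 0.0035, with 11 not detected. Of the 14, 9 had a mean expected count of at least 10, so not detected does not mean absent. Malat1, an RNA of nuclear speckles, stood at 258 ± 178, Neat1, the scaffold of paraspeckles, at 18.8 ± 15.4, and Xist, which coats the inactive X chromosome, at 1.45 ± 0.247. The cytoplasmic median exceeded the nuclear one by 4.58 ± 0.51 on the log2(TPM + 0.1) scale. That difference was 2.87 with a pseudocount of 1 and 2.02 in CPM. Over members at a TPM of 1 or more, of which the nuclear list keeps 3, the direction turned to -0.60 ± 1.61.

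The other noncoding and housekeeping groups spanned a wide range. The 7 lipid A-linked long noncoding RNAs had a median of 0.340 ± 0.184 (n = 2), led by Mir155hg, the host gene of Mir155, at 6.09 ± 3.10. The 15 structured noncoding RNAs had a median of 35.7 ± 13.2 and the 67 replication-dependent histone genes one of 2.03 ± 0.962. The 13 mitochondrial messages had a median of 115 ± 39.5, led by mt-Atp8 and mt-Co1, of ATP synthase and cytochrome oxidase, at 820 ± 316 and 559 ± 212. The 85 cytosolic ribosomal protein genes had a median of 160.3 ± 43.5, led by Rpl41 and Rps24 at 821 ± 233 and 660 ± 251.

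Most genes had similar levels in the 2 replicates. Over the 9302 detected genes the SD per library was 0.24 on the log2(TPM + 1) scale, a factor of 1.18, and 98.6% of genes lay within 2-fold. Protein-coding genes alone gave 0.21. The median log2 ratio of replicate 2 to replicate 1 was -0.12, and the common biological coefficient of variation in edgeR was 0.198. Above a mean TPM of 100 the SD was 0.53 over all genes and 0.30 over protein-coding genes, and 19 small nuclear RNA genes lie in that range.

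The genes that differed most between the replicates included predicted genes with Gm symbols, small nuclear RNA copies, Pde2a, Nnt and Zbed6 under gene entries that overlap others, and mt-Co2, a cytochrome oxidase subunit encoded in mitochondria. A two-sided exact binomial test on 13298 genes, which compares these libraries and not conditions, called 739 genes at least 2-fold apart, 429 higher and 310 lower in replicate 2. Only 83 of the 739 had a mean TPM of at least 10. In the read-based table the binomial test called 1089, 723 higher and 366 lower, of which 550 were among the 739. With a coefficient of 0.1, fixed beforehand, edgeR's exact test called 520, 296 higher and 224 lower. Of the 20 named by fold, 12 were at least 2-fold apart in the same direction in the read-based table, 18 had no count in a library after rounding and 13 overlap another annotated gene, so that reads may be shared. Gm37376, on chromosome 19 from 5801941 to 5802393 inside Malat1 on the opposite strand, had 0 and 324 expected counts in replicates 1 and 2, at least 143-fold higher in replicate 2 against a floor of 3 counts per library (exact binomial adjusted p = 4.3e-118). That bound holds for the alignment-based table alone, since the read-based table gave 555 and 1588 counts, a log2 ratio of 1.86. mt-Co2 had 0 and 213 counts, at least 94.2-fold higher (exact binomial adjusted p = 1.5e-77), although the read-based table gave it 305 and 2506. Gm14440 had 264 and 0, at least 66.3-fold lower in replicate 2 in the alignment-based table alone (exact binomial adjusted p = 1.1e-63), since the read-based table gave 31.0 and 0.334 counts, a log2 ratio of -5.64. Nnt and Zbed6, at least 7.29-fold and 7.79-fold lower in replicate 2, had read-based counts of 399 and 199, a log2 ratio of -0.66, and of 0.114 and 9.3e-05, too few to test. A longer Nnt entry that contains the named one stood at a TPM of 2.6 and 2.52 in replicates 1 and 2. The named entry stood at 0.08 and 0. Pde2a, at least 24.3-fold higher, had read-based counts of 23.1 and 51.6. Gm24407, a small nuclear RNA copy, had 2 and 35 counts, a ratio of 23.2 with a 95% exact counting interval of 5.97 to 199, and 11.0 and 58.4 in the read-based table. Whether counting used strand is not given in the sources used here, so genes antisense to another are uncertain. With simulated counts in which no gene was changed and the coefficient of variation was 0.2, close to the measured 0.198, the binomial test called 369 of 13302 genes and edgeR's exact test called 254 with a coefficient of 0.1 and 0 with 0.2. On the real counts edgeR's exact test with a coefficient of 0.2 called 137 genes, 92 higher and 45 lower in replicate 2. The 0.2 is close to the coefficient measured on these same libraries. The simulation gave every gene the same variation and no reads shared between genes. The 137 and the simulated 0 therefore do not show that these genes differ beyond replicate noise.

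By their list medians, cytokine, chemokine and immediate early messages were lower in replicate 2, and mitochondrial messages and nuclear-retained RNAs were higher. Ribosomal protein messages, histone messages and cytoplasmic long noncoding RNAs were also lower, by less. Few mitochondrial messages were called singly. Relative to the median of all detected genes, the list medians of log2 ratios were -0.68 for cytokines, -0.54 for chemokines and -0.55 for immediate early genes. The exact binomial test called 10 of 20 tested cytokine genes lower and 0 higher, 5 of 17 chemokine genes lower and 0 higher, and 6 of 19 immediate early genes lower and 0 higher, with the same counts when adjusted over the list alone. That test holds counting error only. The coefficient of 0.2 used beside it is close to the 0.198 estimated from these same libraries, so its calls and p-values describe this pair alone. With it, edgeR's exact test called 3 cytokine genes (Il6, Csf2 and Il23a) and 1 chemokine gene (Cxcl1), all lower in replicate 2. It also called 2 immediate early genes (Nr4a1 and Fosb), both lower. Of these Csf2, Il23a, Cxcl1 and Nr4a1, and below Marco, Dusp4 and Hist1h3h, were chosen after their values were seen. Il6 was 2.97-fold higher in replicate 1 (edgeR exact test with a coefficient of 0.2, adjusted p = 0.0257) and Il10 5.19-fold higher (edgeR adjusted p = 2.4e-05). Other examples were Cxcl1, a neutrophil attractant, 4.62-fold higher in replicate 1 (edgeR adjusted p = 0.000101), Nr4a1, an orphan nuclear receptor, 5.83-fold (edgeR adjusted p = 4.7e-06), Csf2, a myeloid growth factor, 6.78-fold (edgeR adjusted p = 1.1e-05), and Marco, a scavenger receptor, 4.33-fold higher in replicate 2 (edgeR adjusted p = 0.000217). Malat1 and Neat1 were 3.23-fold and 3.49-fold higher in replicate 2 (edgeR adjusted p = 0.00882 and 0.00383). Effector genes lay at 0.25, with 6 of 23 tested called higher and 1 lower by the binomial test and Marco alone by edgeR at 0.2. Feedback genes lay at -0.01, with 2 of 24 higher and 3 lower by the binomial test and 2, Il10 and Dusp4, lower by edgeR at 0.2. Ribosomal protein genes lay at -0.40 and NF-kB genes at -0.23, with 0 of 83 and 0 of 18 called by the binomial test. Histone genes lay at -0.40, with 12 of 62 called lower, and cytoplasmic long noncoding RNAs at -0.37, with 1 of 10 called lower. The ratio itself had a median of -0.12 over all detected genes. On it, 82 of 82 detected ribosomal protein genes were lower, as were 37 of 42 histone genes and 10 of 10 cytoplasmic RNAs. Mitochondrial messages lay at 0.84. By the ratio itself, not taken relative to all genes, 11 of 12 detected were higher. The binomial test called 2 of 13 tested higher, and edgeR at 0.2 mt-Co2 alone. Nuclear-retained RNAs lay at 1.65 over 3 detected genes, of which Xist was lower, with 3 of 9 tested called higher by the binomial test and 2, Malat1 and Neat1, by edgeR at 0.2. Neutrophil markers lay at 0.57 with 4 of 6 called higher, structured RNAs at 0.22 with 4 of 11 higher, alternative activation genes at 0.31 with 2 of 10 higher and 2 lower, and macrophage identity genes at 0.11 with 2 of 24 higher, all by the binomial test. Cholesterol and lipid genes lay at 0.20, and at 0.08 by the ratio itself, on which 10 detected members were higher and 9 lower. The 2 of 20 called were both lower. Antigen presentation genes at 0.32, lysosomal genes at 0.19 and interferon-stimulated genes at 0.06 had 0 called. By the ratio itself, interferon-stimulated genes lay at -0.06 and macrophage identity genes at -0.007. In the lists from the ribosomal to the interferon-stimulated genes edgeR at 0.2 called, beside the genes named for it, Rmrp higher and Hist1h3h lower. Proliferation genes at 0.10, glycolysis genes at -0.03 and TLR4 pathway genes at -0.03 lay with the feedback genes inside the central 95% of 10000 random lists matched on expression, while the other 18 of 22 lists lay outside it. These percentiles describe the 2 libraries. With TMM-scaled CPM the macrophage identity, interferon-stimulated, lysosomal and structured RNA lists fell inside that range and proliferation genes, at 0.23, outside it. In the read-based table the NF-kB, alternative activation and macrophage identity lists fell inside it and proliferation genes, at 0.34, outside it, and the macrophage identity and interferon-stimulated lists turned to -0.01 relative to all genes.

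**Figure D3:**
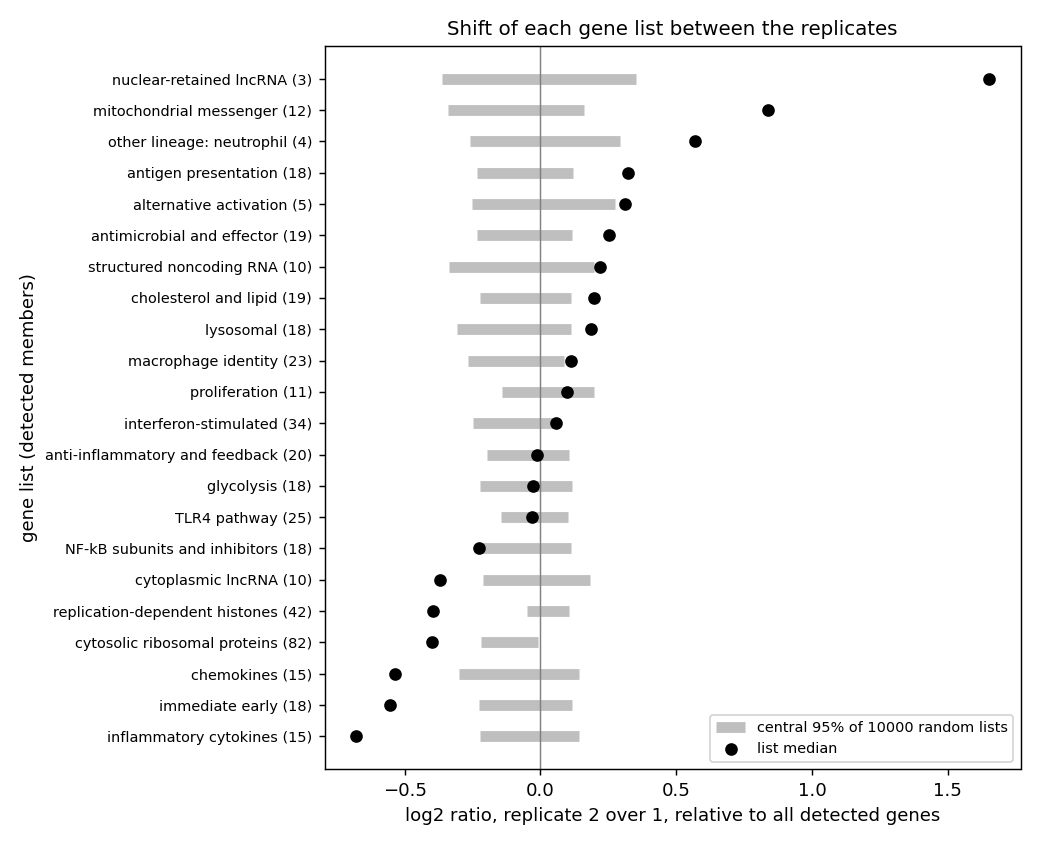
Median log2 ratio of replicate 2 to replicate 1 for each gene list, relative to all detected genes, as points, with the central 95% of 10000 random lists matched on expression as grey bars and detected members in brackets. Cytokines lay lowest at -0.68 and nuclear-retained long noncoding RNAs highest at 1.65.

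Most abundant response genes were represented by a single leading transcript. Of 157 genes in the 7 response lists 118 had a mean TPM of at least 10, and in 80 of these the leading transcript held at least 80% of the gene's TPM in both replicates. In 20 of the 118 genes the annotation has 1 transcript, so that the share is fixed. Tnf-201 held 99.99% ± 0.00031 (n = 2), Ccl5-201 99.7% ± 0.117, Saa3-201 99.9% ± 0.013 and Nfkbia-201 99.5% ± 0.408. For these 20 genes the 2 transcript tables had to agree. With them included, the tables named the same leading transcript for 112 genes and different ones for 6. The latter included Ifih1, a sensor of viral RNA, with Ifih1-201 leading at 65.5% ± 3.79 in the alignment-based table, and Nfkb2, an NF-kB subunit, with Nfkb2-201 leading at 56.6% ± 0.167. The leading transcript was not annotated as protein-coding for 5 genes, among them Sod2-207 at 52.1% ± 0.247, Oasl2-205 at 61.8% ± 2.59 and Mx1-205 at 52.9% ± 1.61, which were picked after their values were seen. Over 8812 detected protein-coding genes, transcripts not annotated as protein-coding held 6.78% ± 0.06 of TPM (n = 2). Retained-intron transcripts held 2.95% ± 0.131, those marked for nonsense-mediated decay 1.70% ± 0.140 and processed transcripts 2.13% ± 0.054. The median share per gene was 1.46%.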

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

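Both results here were picked out because they hold counts in data that the comparisons do not use, above the limit that a count of 0 allows. Counts on the genome of phage phiX, a common sequencing control, were 70745 in replicate 1 and 55270 in replicate 2, while all 96 ERCC spike-ins had 0 counts in both. In the read-based table, 8 genes with no count in the alignment-based gene table held 6.21% of estimated counts in replicate 1 and 11.6% in replicate 2. Most lay on Gm12895 and Gm12896, processed pseudogenes of 226 bases on chromosome 4, with estimated counts of 1915450 each, to 6 digits, in replicate 1 and of 3185920 on Gm12896 and 3184690 on Gm12895 in replicate 2. The 8 are the genes above a minimum of read-based counts in both libraries, and genes with fewer were left out. The lowest count among the 8 was 1403, on Gm20400 in replicate 2.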

How the results depend on the processing

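Alternatives chosen after seeing the data were edgeR at a coefficient of variation of 0.2, protein-coding genes only, TPM rescaled to protein-coding genes, ratios relative to all detected genes and gene levels from the read-based table. The cause was not tested for any change below. Detected genes numbered 5569 at a TPM of 5 and 7965 in the read-based table. They numbered 11174 with TPM rescaled to protein-coding genes and 12815 at an expected count of at least 10 in both replicates. Replicate spread (log2) was 0.28 with a pseudocount of 0.1 and 0.28 with 0.01, 0.21 with no filter (0.205), 0.28 at a TPM of 10, 0.23 with TMM-scaled counts and with DESeq2 size factors, 0.25 (0.246) in the read-based table and 0.21 in protein-coding genes. Differing genes numbered 224 at a mean count of 100, where fewer genes are tested, and 137 with edgeR at 0.2. The cytosolic against nuclear contrast was 2.87 with a pseudocount of 1, 2.02 in CPM, 3.29 with list means, 3.48 in the read-based table and -0.60 over members at a TPM of 1 or more. The macrophage contrast was 7.25 with a pseudocount of 1, 12.61 with 0.01, 11.13 in FPKM, 11.38 in CPM, 6.51 over members at a TPM of 1 or more, 9.49 with list means and 9.79 in the read-based table. The effector contrast was 2.40 over members at a TPM of 1 or more, and the immediate early contrast was -2.12 in CPM and -2.15 with list means. Of the levels of the 16 preset genes, all were moved by rescaling TPM to protein-coding genes and 9 by the read-based table, by more than the SD between replicates. Tnf went from 1032 to 3645 and 520, Cxcl10 to 2420 and 337, Acod1 to 3010 and 450, and Tlr4 to 59.7 and 8.91. Leading transcripts numbered 51 at a gene TPM of 50, where fewer genes are counted. The share of transcripts not protein-coding was 7.50% in the read-based table, 6.44% at a TPM of 10 and 1.46% as a median per gene. Of the 18 lists outside the central 95%, 17 were so with a pseudocount of 0.1, 14 with TMM-scaled CPM and 14 in the read-based table, which gave a value for 21 lists. There the median of all genes was -0.44, and the macrophage identity and interferon-stimulated shifts were -0.45 and -0.45. Leaving out each replicate gave 9507 to 9643 detected genes and contrasts of 4.22 to 4.93 (cytosolic), 10.37 to 10.40 (macrophage), 0.77 to 2.02 (effector) and -1.75 to -1.43 (immediate early), with 81 to 84 leading transcripts and shares of 6.73% to 6.82%. Without replicate 1 the effector contrast was 2.02, and without replicate 2 it was 0.77. No paired analysis was possible because there is 1 group.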

Other observations

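The test of nuclear RNA for the early response genes and the comparison with genes of similar length and the separate test of preset members for the nuclear RNAs were chosen after the results were seen. The other tests were chosen before their own results were seen, though both patterns were found in these libraries.

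Detected cytokine, chemokine and immediate early genes, 48 in all, were lower in replicate 2 relative to all detected genes in 43 cases, with a median log2 ratio of -0.55. A trend on transcript length, GC content and expression is argued against by a residual of -0.54, which keeps 97.4% of the shift. More nuclear RNA in replicate 2 cannot be told apart from other explanations. The retained-intron share of these genes was 0.197% in replicate 1 and 0.352% in replicate 2, a ratio of 1.79, but no nuclear library was analysed here to show how nuclear RNA would move them. The test also required a median log2 ratio that was not negative, and these genes were taken up because theirs was. It could therefore not have favoured nuclear RNA. No biological explanation was tested, because the design gives 1 group, and differences in timing or handling between the replicates stay open.

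Nuclear noncoding RNAs were higher in replicate 2 in 6 of 7 detected cases, the exception being Xist, but 4 of the 7 (Rn7sk, Rmrp, Rpph1 and Rnu12) were added after their values were seen. A trend on transcript length, GC content and expression is argued against as the whole cause for Malat1 and Neat1, fixed beforehand, whose residuals of 1.63 and 1.87 lay above the central 95% of those of genes of similar length (upper limits of 0.446 and 0.476). With Xist, at -0.09 before and 0.03 after the correction, the median of the preset members is the value of Malat1, 1.65 before and 1.63 after. For the added members the trend is left open, although the median residual of all 7, 1.22, met the bound set beforehand and kept 77.1% of the shift: Rn7sk lay above its limit (1.22 against 0.960), but Rmrp, Rnu12 and Rpph1 lay inside theirs, as did Xist, and genes of about the length of Rnu12 had a median log2 ratio of 1.72 relative to all detected genes. More nuclear RNA in replicate 2 cannot be told apart from other explanations, because the retained-intron share of protein-coding genes differed by a ratio of 1.06, replicate 2 over 1, between the bounds set beforehand. Of 45 small nuclear and nucleolar RNA genes 42 were higher in replicate 2, and 19 of the 45 have a transcript identical in sequence to that of another gene. The genes of similar length were not separated by class and may include such RNAs. For Rnu12 that comparison therefore cannot tell length from nuclear RNA. No biological explanation was tested.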
